A study of Mus musculus with 8 samples.

How the data were processed

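Gene expression was measured by RNA sequencing in 8 mice aged 12 months, 4 wild type and 4 Dclk3 knockout, with 1 striatum per library. Per the labels' protocols, libraries were made from 1000 ng of RNA with poly(A) selection and a stranded kit that marks the second cDNA strand with dUTP, and were amplified for 12 PCR cycles, with no molecular identifiers mentioned. Poly(A) selection measures polyadenylated transcripts, so RNAs without a poly(A) tail are seen only as carry-over.

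The authors deposited 1 table of whole-number read counts per Ensembl gene, with a column for each library that its header marks as raw, and no normalized values were used. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17.1.14 and the genome build was mm10. The aligner, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Where genes overlap or have near-identical copies, the way reads were assigned is therefore open. Of the genes named here under the rule below, Aldh1l1, Slc1a3, Mobp, Abcb1a, Slc17a7, Prkar1b, Syn1, Dclk1, Map1b, mt-Nd1, mt-Nd2, Manf, Srebf2, Oxsr1, Rpl23, Ddx3y and Ptpn5 overlap another annotated gene on the same strand; for others the overlap is given beside their values. Ebf1, Cux2, Rora, Plekhg1, Alas2, Junb, Dcdc2a, Kif5b, Irf7, B2m and Bdnf overlap one on the opposite strand only. Their values can include reads of the other gene. The table lists 31417 genes, of which 2001 had no count in any library.

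Gene symbols and positions came from the GENCODE annotation of GRCm38, the assembly that mm10 names, supplied for this work. Of the gene identifiers, 31292 matched and 125 did not, and the unmatched ones held 0.044% of the counts. The 0 counts of a gene were compared with a floor of 3 counts, which corresponds to between 0.0808 and 0.123 CPM depending on the library. Total counts ran from 24441242 to 37145559 per library. Floors and intervals of this kind cover counting error only, since PCR copies are not independent molecules. Pairs of libraries of the same genotype differed by chi-square values of 7.07 to 32.1 per degree of freedom over 12 pairs, so no pair within a genotype was a copy. Pairs across the genotypes were not compared in this way.

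Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 16511 genes and removed 14906, and libraries were scaled by TMM. A robust quasi-likelihood model with genotype as the only term was fitted to all 8 libraries, and two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are knockout over wild type, with the standard error and 95% interval derived from the quasi-likelihood statistic, and group values are means of TMM-scaled CPM ± SD. For Dclk3 alone an exact permutation test over the 70 assignments of the libraries was added.

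Before the data were examined, 36 gene lists were fixed, covering striatal neurons, other cell types of the striatum and of adjacent tissue, signalling and chromatin pathways, and the neighbours of Dclk3. One list of sex-linked genes served only as a check, and the other 35, holding 619 genes of which 22 are in more than 1 list, were tested with camera in limma 3.58.1. Camera used log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and lists needed at least 5 measured members. Camera with an estimated correlation and fry were run beside it. A list score is the mean, over the measured members, of each library's log2 CPM minus the mean of the 8 libraries. The genes named in the text were set by a rule fixed at the same time. It names Dclk3, the 5 genes with the smallest p and, of genes past the threshold with a mean of at least 1 CPM and no overlap between the genotypes, the 12 higher and the 12 lower with the largest change, predicted genes taking no place. When fewer than 10 genes pass, as here, it names all of them and the 10 with the smallest p that do not. In each list it names up to 4 measured members, those with the smallest p, and any past the threshold. Some genes that the rule names are not reported here. Genes named outside it are said to have been chosen after their values were seen.

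The analysis was tested on simulated data. Counts for 16511 genes were drawn with the means, dispersions and library sizes of these data, in 5 draws, and 5.4% of 703 calls were false, while camera called 0 of 100 unchanged lists and 5 of 5 lists raised 1.3-fold. Simulated genes vary independently, so the test says nothing about lists whose members vary together between animals.

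Alternatives fixed before the data were examined were DESeq2's size factors and upper-quartile scaling in place of TMM, no filter and a filter of 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test with its own filtering in place of filterByExpr, limma-voom with quality weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a non-robust fit, an adjusted p threshold of 0.1 and leaving out each library in turn. Chosen after seeing the data were the choroid plexus and thalamic scores as covariates, the odd or even replicate number as a covariate, leaving out replicate 4 of each genotype together, the DESeq2 test on the filtered genes, camera on all genes within 5 and 10 Mb of Dclk3, and Fisher tests of genes with an unadjusted p under 0.05 in these windows. Fisher tests of genes past the threshold in the same windows had been fixed before. Alternatives planned for normalized values did not apply, since the table holds counts. Figures were drawn with matplotlib 3.10.9.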

Results

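RNA was sequenced from the striatum of 12-month-old mice, with 4 wild-type controls and 4 Dclk3 knockouts. The striatum is the main input nucleus of the basal ganglia, and most of its neurons are GABAergic medium spiny neurons. Each library was made from the striatum of a single mouse, so the replicates are animals, and the comparison asks how gene expression in the adult striatum differs when Dclk3 is knocked out. Total gene counts were 29487290, 35673708, 28776767 and 37145559 in wild-type replicates 1 to 4 and 24441242, 27954259, 34919463 and 27229000 in knockout replicates 1 to 4. The first principal component of expression held 26.8% of the variance and placed wild-type replicate 4 (29.9) and knockout replicate 4 (-23.5) at its ends, with no separation of the genotypes.

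Dclk3 itself was strongly reduced in the knockout. Dclk3 (ENSMUSG00000032500) encodes doublecortin-like kinase 3, a serine/threonine kinase enriched in the striatum, and lies on the plus strand of chromosome 9 at 111439081 to 111489118 in the GRCm38 (mm10) assembly. Its expression was 95.2, 117, 80.9 and 86.1 CPM in wild-type replicates 1 to 4 and 27.7, 19.6, 20.9 and 22.7 CPM in knockout replicates 1 to 4. The means were 94.7 CPM ± 15.8 (SD, n = 4) and 22.7 CPM ± 3.55 (SD, n = 4), so that the knockout kept 24.0% of the wild-type level, with single libraries between 20.7% and 29.3%. The log2 fold change was -2.06 (SE 0.14, 95% interval -2.37 to -1.76), a 4.18-fold lower level, with an adjusted p of 0.000773 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All knockout libraries lay below all wild-type libraries, and the exact two-sided permutation test over the 70 assignments gave p = 0.0286, the smallest value this design allows. Between 546 and 728 counts per library remained over the gene in the knockout. The deleted part of the gene is not given in the sources used here, and the deposited values are sums over the whole gene, so they do not show from which exons the remaining counts came.

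**Figure D1:**
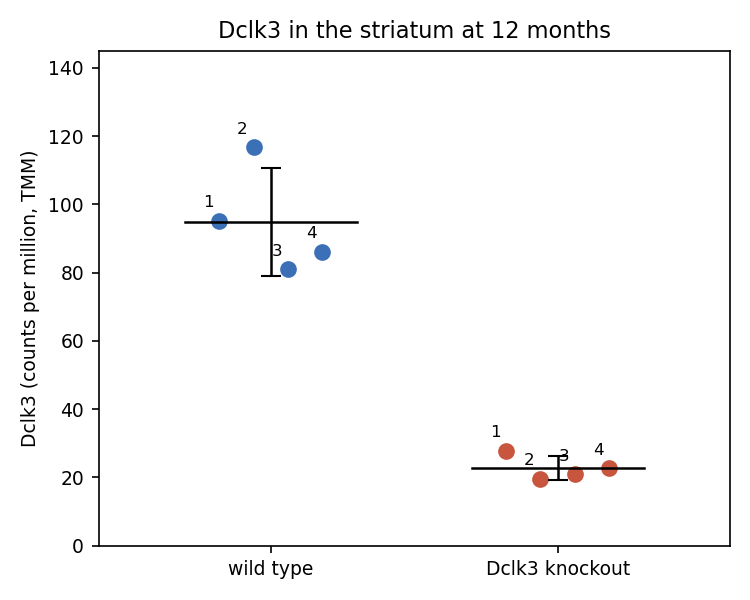
Dclk3 expression in CPM (vertical axis, TMM-scaled) in each of the 4 wild-type and 4 knockout striata; the number beside a point is the replicate, the horizontal line the mean and the bar 1 SD. The knockout libraries lie between 19.6 and 27.7 CPM and the wild-type libraries between 80.9 and 117 CPM.

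Among 16511 genes tested, Dclk3 was the 1 gene past an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 0 genes higher and 1 lower in the knockout. At an adjusted p of 0.1 the count was again 1. An unadjusted p under 0.05 was reached by 620 genes, 324 higher and 296 lower, where chance alone would give 826. The DESeq2 Wald test without the filter on low counts (29371 genes) called 3 genes, Dclk3, Malat1 and 1520401A03Rik, and on the filtered genes, a setting chosen after seeing the data, it called 2, Dclk3 and Malat1. EdgeR with no filter on low counts called 1 gene, Malat1, and left Dclk3 at an adjusted p of 0.0647 with a log2 fold change of -2.07. Without wild-type replicate 1 edgeR called 2 genes, Dclk3 and 1520401A03Rik, a gene outside the naming rule that was chosen after its values were seen.

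The gene with the next smallest p was Malat1, an abundant long non-coding RNA retained in the nucleus. It measured 415 CPM ± 33.5 (SD, n = 4) in wild type and 620 CPM ± 79.3 (SD, n = 4) in the knockout, a log2 fold change of 0.58 (SE 0.09). All 4 knockout libraries lay above all 4 wild-type libraries, but its adjusted p was 0.286 (edgeR quasi-likelihood, Benjamini-Hochberg), so it did not pass the threshold. In the DESeq2 Wald test its adjusted p was 4.06e-05 without the filter and 2.76e-05 on the filtered genes, and over 21 alternative settings the adjusted p ranged from 2.76e-05 to 0.999 while the log2 fold change stayed between 0.49 and 0.64. The annotation places another gene on the same strand and one on the opposite strand within its span, and the strand setting of the counting is not given in the sources used here.

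The other genes among the 10 with the smallest p all had an adjusted p of 0.999 (edgeR quasi-likelihood, Benjamini-Hochberg). Gjb6, which encodes the astrocyte gap junction protein connexin 30, measured 38.5 CPM ± 2.30 in wild type and 51.1 CPM ± 7.56 in the knockout (SD, n = 4 each), a log2 fold change of 0.41. Prom1, a membrane glycoprotein gene, had a log2 fold change of 0.34, and Clec2d, a C-type lectin gene, one of 0.54. Dhx58, which encodes the RNA sensor LGP2, had a log2 fold change of 0.86 between 0.935 and 1.71 CPM, and Npsr1, the neuropeptide S receptor, one of -0.80 between 4.02 and 2.31 CPM. Tecrl (1.26), Gm44200 (0.91), 3425401B19Rik (1.21) and G530011O06Rik (1.41) were measured at low levels. Dhx58, Gm44200, Npsr1, Prom1, Tecrl and G530011O06Rik overlap other annotated genes, so their counts can include reads of those genes.

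**Figure D2:**
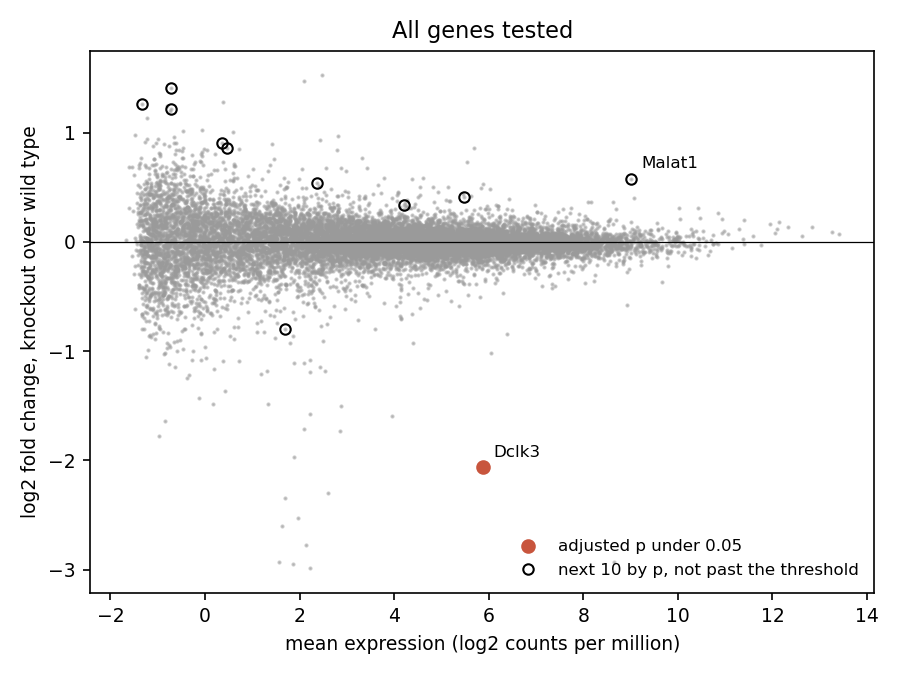
Log2 fold change of knockout over wild type (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 16511 genes tested, 4 libraries per genotype. Dclk3, at -2.06, is the filled point past the adjusted threshold; the open circles are the 10 genes with the next smallest p, Malat1 among them at 0.58, none past it.

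The interval widths set what such a count can exclude. The 95% interval of the fold change lay within 1.5-fold in either direction for 77.8% of the genes and within 2-fold for 93.5%, and the common biological coefficient of variation was 11.1%. In simulated data with the same library sizes and 16511 genes, the test recovered 22.5% of 1.25-fold, 64.3% of 1.5-fold, 81% of 2-fold and 99.6% of 4-fold changes. Those data held 250 changed genes of each size over 5 draws. With many changed genes the adjusted threshold is easier to reach, so these shares can be too high where few genes change. Simulated genes also varied independently of each other.

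Calls for the gene lists fixed for the tissue depended on the inter-gene correlation assumed. Camera compares the mean test statistic of the members of a list with that of all other genes. A list said to rank higher or lower had a higher or lower mean statistic, and no rank test was used. With its preset inter-gene correlation of 0.01, camera put 10 of 35 lists past an adjusted p of 0.05, 7 ranked higher and 3 ranked lower. With an estimated correlation 0 of the 35 lists passed, and 2 had an unadjusted p under 0.05. Fry, whose directional p tests whether the members move on balance in a single direction and whose mixed p tests for change in either direction, passed 0 lists with each p, and 2 lists had an unadjusted mixed p under 0.05. Over 18 alternative settings with the preset correlation, 2 of the 10 lists, astrocyte and endothelial markers, kept their call in all, and of the 25 other lists 14 passed in at least 1 setting, 5 of them in both directions. Without wild-type replicate 2, 16 lists passed. Over all genes tested, 0 members of any list passed the threshold.

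Astrocyte markers ranked higher in the knockout (camera adjusted p = 6.26e-06; adjusted p = 0.523 with an estimated correlation). Of 12 measured members 10 lay above 0, with a median log2 fold change of 0.15, and 1 member, Gjb6, passed when adjusted over the list alone (adjusted p = 0.0135, edgeR quasi-likelihood). Slc1a3, a glutamate transporter, had a log2 fold change of 0.17, Slc4a4, a bicarbonate transporter, 0.18, and Aldh1l1, a folate enzyme, 0.16. Endothelial markers also ranked higher (camera adjusted p = 0.000254; adjusted p = 0.523 with an estimated correlation), with 8 of 10 members above 0, a median of 0.22 and 0 members past the threshold adjusted over the list alone. Among them Slco1a4, an organic anion transporter of the blood-brain barrier, had 0.27, Abcb1a, the efflux pump P-glycoprotein, 0.37, and Ly6c1 0.43. The Ly6c1 value rested mainly on knockout replicate 4, at 28.87 CPM. Knockout replicates 1 to 3 had 16.61, 14 and 17.25 CPM of Ly6c1, and the wild-type libraries 13.09 to 14.99 CPM.

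Oligodendrocyte and myelin markers ranked higher with 12 of 12 members above 0 and a median of 0.19 (camera adjusted p = 4.74e-06; adjusted p = 0.757 with an estimated correlation). The myelin protein gene Mobp had a log2 fold change of 0.31, and 0 members passed adjusted over the list alone. The call was lost with 1 surrogate variable in the model (camera adjusted p = 0.252), and so was that of blood cell markers (adjusted p = 0.0552). Blood cell markers had 5 of 5 measured members above 0 and a median of 0.48 (camera adjusted p = 3.34e-05; adjusted p = 0.523 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. The haemoglobin genes Hbb-bs and Hbb-bt had values of 0.48 and 0.67 and the haem enzyme gene Alas2 0.67, and since Hbb-bs and Hbb-bt are near-identical copies, counting could have divided their reads between them. The blood score was 0.695 in knockout replicate 1 and 0.471 in knockout replicate 4, and between -0.684 and -0.0612 in the other 6 libraries. Microglia markers had 11 of 11 members above 0 with a median of 0.070 (camera adjusted p = 0.0141; adjusted p = 0.757 with an estimated correlation), C1qa at 0.18 and Tmem119 at 0.11, and 0 members passed adjusted over the list alone. The microglia call was lost in 6 of 18 settings: without wild-type replicate 4, without knockout replicate 4, without both, with limma-voom, with 1 surrogate variable, and with the choroid plexus and thalamic scores as covariates.

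Mitochondrially encoded transcripts ranked higher, with 7 of 7 measured members above 0 and a median of 0.12 (camera adjusted p = 0.00449; adjusted p = 0.757 with an estimated correlation). The list holds 13 transcripts, so the call does not cover those that were not measured. The complex I subunits mt-Nd1 and mt-Nd2 had log2 fold changes of 0.14 and 0.18, and 0 members passed adjusted over the list alone. The call was lost with 1 surrogate variable and without replicate 4 of both genotypes (highest adjusted p 0.145). Thalamic and other subcortical glutamatergic markers had 10 of 10 members above 0 and a median of 0.43 (camera adjusted p = 0.0141; adjusted p = 0.757 with an estimated correlation). Plekhg1 had a log2 fold change of 0.50 and the nuclear receptor gene Rora 0.24, with 0 members past the threshold adjusted over the list alone. The thalamic score was 1.17 in knockout replicate 4 and 0.517 in knockout replicate 1 but -0.359 and -0.636 in knockout replicates 2 and 3, and this list lost its call in 7 of 17 settings: without wild-type replicate 3 or 4, without knockout replicate 1 or 4, without replicate 4 of both genotypes, with limma-voom and with 1 surrogate variable. The setting that adjusts for the list's own score is left out of this count.

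Activity-regulated immediate early genes ranked lower, with 12 of 16 members below 0 and a median of -0.23 (camera adjusted p = 0.000254; adjusted p = 0.757 with an estimated correlation). The transcription factor genes Egr4, Junb, Nr4a3 and Egr3 had log2 fold changes of -0.69, -0.61, -0.46 and -0.28, and 0 members passed adjusted over the list alone. The score was -0.628 in knockout replicate 1 against -0.0794, 0.0551 and 0.159 in the other knockout libraries, and the call was lost without knockout replicate 1 and with 1 surrogate variable. Cholesterol synthesis genes had 16 of 17 members below 0 and a median of -0.13 (camera adjusted p = 0.000289; adjusted p = 0.757 with an estimated correlation), with Sqle at -0.17 and the transcription factor gene Srebf2 at -0.16. Their call was lost in the same 6 settings as that of microglia, and 0 members passed adjusted over the list alone. Ependymal markers had 7 of 7 measured members below 0 and a median of -0.18 (camera adjusted p = 0.00651; adjusted p = 0.523 with an estimated correlation), Tekt1, a cilium protein gene, had -0.53, and 0 members passed adjusted over the list alone. The ependymal call was lost without wild-type replicate 4 and without knockout replicate 3.

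Lists of genes that define striatal neurons had median log2 fold changes between -0.018 and 0.073. Of the 26 medium spiny neuron identity genes, 23 lay above 0, within -0.14 to 0.12 on the log2 scale and with a median of 0.027 (camera adjusted p = 0.092). Camera placed this list higher past the threshold in 6 of 18 alternative settings, with adjusted p down to 6.85e-05 without wild-type replicate 1. Bcl11b, a transcription factor gene of spiny neurons, had -0.14, Kcnip2, a potassium channel subunit gene, 0.12, and Ptpn5, the striatal-enriched phosphatase, 0.10. Direct-pathway markers, such as Tac1 (0.16) and Ebf1 (0.19), had a median of -0.018 and a mean of 0.039, and camera placed the list higher (adjusted p = 0.543). Indirect-pathway markers, such as Gpr6 (-0.08), had a median of 0.0045 and a mean of -0.052, and camera placed the list lower (adjusted p = 0.759). Striatal interneuron markers had 8 of 11 members above 0 and a median of 0.073 (camera adjusted p = 0.101, past the threshold in 4 of 18 settings), with Pvalb at 0.49, Npy at 0.15 and Sst at -0.31. Members of the interneuron list ran from -0.34 to 0.49. Pvalb was at 84.75 and 77.78 CPM in knockout replicates 1 and 4. In knockout replicates 2 and 3 it was at 47.43 and 56.08 CPM, and in wild type at 44.6 to 52.41 CPM. In each of these 4 lists 0 members passed adjusted over the list alone.

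Signalling and synaptic lists had medians close to 0 as well. Dopamine and cAMP signalling, with Prkar1b at -0.11, had a median of -0.0065 (camera adjusted p = 0.543), and glutamate and GABA receptors, with Grik1 at 0.14, had 0.018 (adjusted p = 0.543). Postsynaptic and plasticity genes had a median of -0.027 (adjusted p = 0.123, lower past the threshold in 3 of 18 settings) with Camk2b at -0.12 and Syn1 at -0.17, ion channels of spiny neurons had -0.025 (adjusted p = 0.543, past the threshold higher in 2 settings and lower in 1) with Hcn2 at 0.13, and neuropeptides and trophic factors had 0.049 but a mean of -0.054 (camera placed them higher, adjusted p = 0.708) with Bdnf at -0.33 and Nptx2 at -0.30. The doublecortin family and related kinases, the relatives of Dclk3, had a median of -0.020 and a mean of 0.0097 (camera placed them lower, adjusted p = 0.758). Among them the paralog Dclk1 measured 951 CPM ± 101 in wild type and 887 CPM ± 109 in the knockout (SD, n = 4 each), a log2 fold change of -0.10 (95% interval -0.31 to 0.11), and Dcdc2a had 0.16. Microtubule and axonal transport genes had a median of -0.028 (adjusted p = 0.643), with Map1b at -0.22 and Kif5b at 0.19. In each of these 7 lists 0 members passed adjusted over the list alone.

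Of the chromatin lists, the SAGA and ATAC histone acetyltransferase complexes had a median of -0.011 and a mean of 0.022, and camera placed them lower (adjusted p = 0.643). Fry's mixed test, in which this list came lowest, gave an adjusted p of 0.143. Its member Taf9 had a log2 fold change of 0.98 at 0.196 and 0.396 CPM, near the lowest levels tested, and overlaps Ak6 in the annotation, and Tada2a had -0.11. Other chromatin regulators had a median of -0.037 (camera adjusted p = 0.051, lower past the threshold in 4 of 18 settings). Of the stress and maintenance lists, the camera adjusted p was 0.577 for nuclear-encoded oxidative phosphorylation (median -0.0012, Cox5b at -0.52, lower past the threshold in 4 of 18 settings) and 0.686 for heat shock and the unfolded protein response (median -0.0029, Manf at -0.22). It was 0.931 for apoptosis and p53 targets (median -0.0100, mean 0.00053, camera placed them lower) and 0.122 for reactive glia and inflammation (median 0.071, past the threshold in 1 setting), in which the interferon regulator gene Irf7 had 0.47 and B2m 0.19. Cytosolic ribosomal protein genes had a median of -0.0039, a mean of -0.0052 and were placed higher by camera (adjusted p = 0.577, past the threshold higher in 2 settings and lower in 1), and several, such as Rpl23 (0.18), have pseudogene copies that can share their reads. In each of these 7 lists 0 members passed adjusted over the list alone.

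Markers of tissue next to the striatum differed between single libraries. All 10 choroid plexus markers lay below 0, with a median of -1.85, but the list was not past the threshold (camera adjusted p = 0.051). Their score was 3.42 in wild-type replicate 4 and between -1.04 and 0.460 in the other 7 libraries, and Aqp1, a water channel gene, turned from -2.78 to 0.12 when wild-type replicate 4 was left out. Without that library the whole list ranked higher (camera adjusted p = 0.0124), and over 17 settings, the adjustment for its own score left out, it passed 7 times lower and 2 times higher. Cortical excitatory neuron markers had a median of -0.15 (adjusted p = 0.0502), with Slc17a7, a vesicular glutamate transporter gene, at -0.36 and Cux2 at -0.18. Their score was -0.529 in knockout replicate 4 and -0.0866, 0.238 and 0.118 in knockout replicates 1 to 3. The cortical list passed lower in 7 of 18 settings, but without replicate 4 of both genotypes, a setting chosen after seeing the data, it passed higher (adjusted p = 0.031). Septal, pallidal and ventral forebrain markers had a median of 0.13 (adjusted p = 0.422), passed higher in 2 settings and lower (adjusted p = 0.0358) without replicate 4 of both genotypes, and mural cell and meningeal markers had 0.082 but a mean of -0.024 (camera placed them higher, adjusted p = 0.0566, past the threshold in 8 of 18 settings) with Vtn at 0.22. Oligodendrocyte precursor markers had a median of 0.042 (adjusted p = 0.708) and subventricular neuroblast markers one of -0.043 (adjusted p = 0.300), with Cd24a at -0.16, and each passed lower in 1 setting. In each of these 6 lists 0 members passed adjusted over the list alone.

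**Figure D3:**
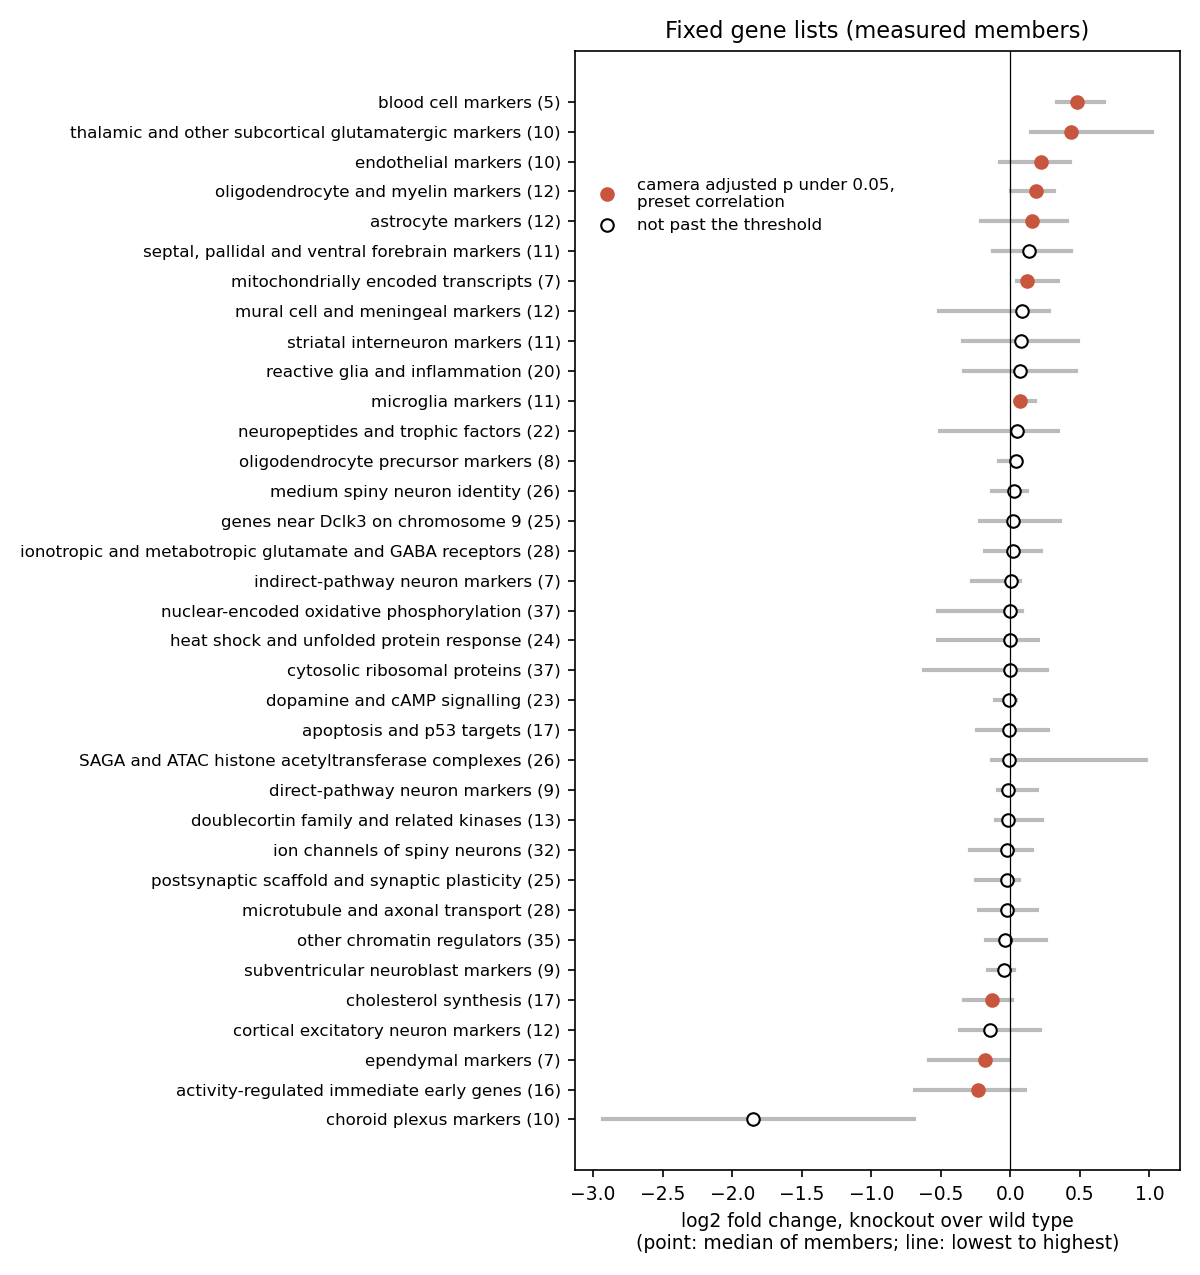
Median log2 fold change of knockout over wild type (points, horizontal axis) and the lowest to highest member (lines) for each of the 35 fixed gene lists, with measured members in parentheses; 4 libraries per genotype. Filled points are the 10 lists past the camera threshold with the preset correlation, of which 0 passed with an estimated correlation.

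**Figure D4:**
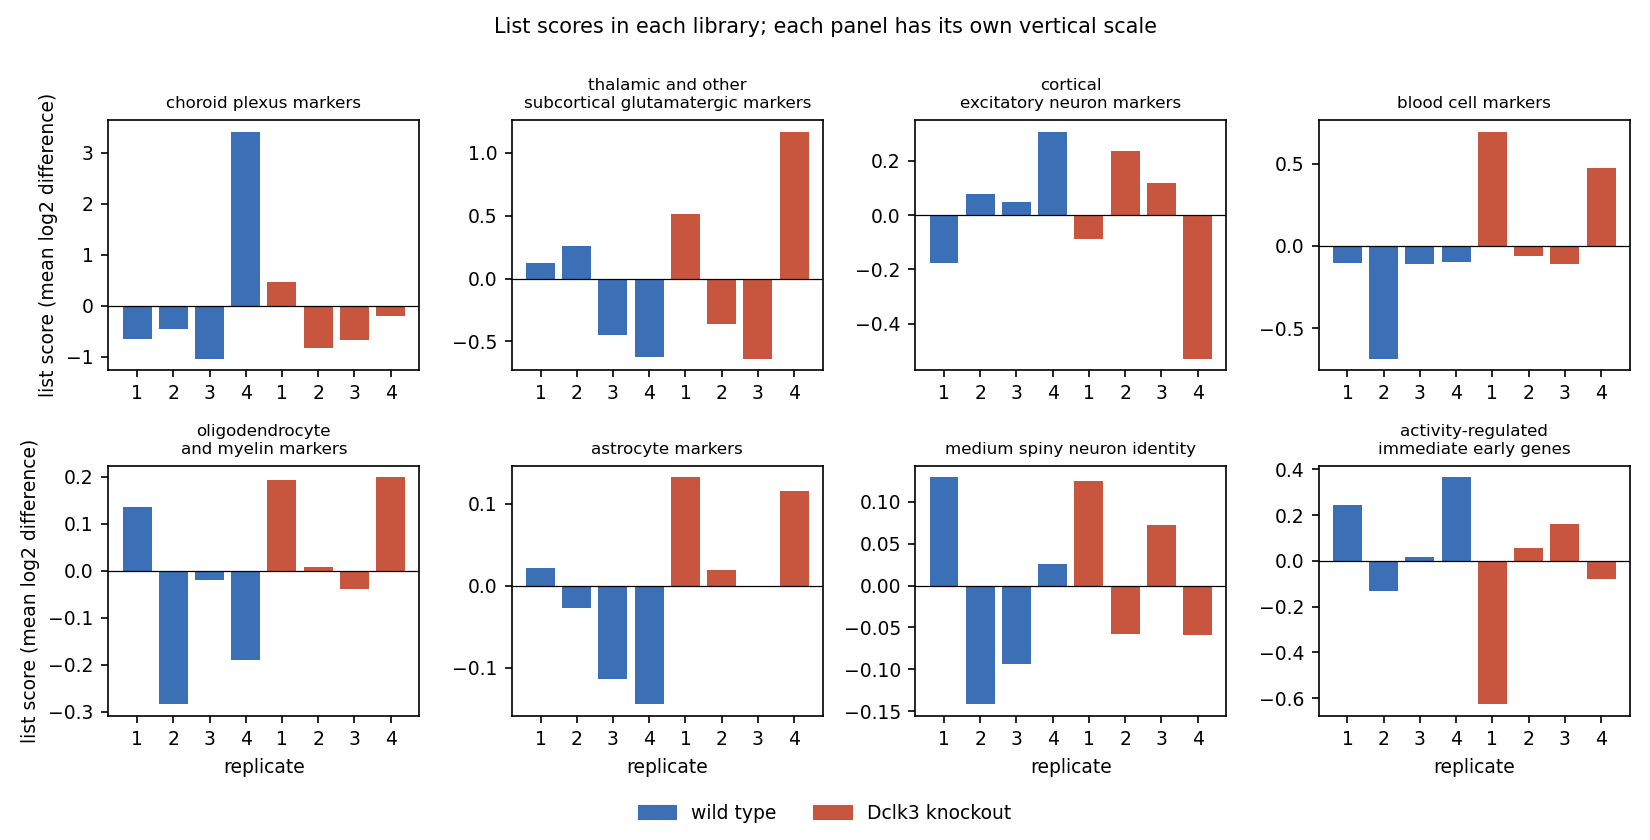
List score in each library (vertical axis, mean log2 difference of the members from their mean over the 8 libraries; bars start at 0 and each panel has its own scale) for 8 gene lists; blue bars are wild type and red bars Dclk3 knockout. The choroid plexus score reaches 3.42 in wild-type replicate 4, and the thalamic score 1.17 in knockout replicate 4.

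Genes near Dclk3 on chromosome 9 were examined because a targeted allele can carry flanking DNA of another strain. The fixed list of neighbours had 25 measured members, a median log2 fold change of 0.021 and 1 member with an unadjusted p under 0.05, Oxsr1 (0.15), while Exog had -0.14. The camera adjusted p was 0.543, and adjusted over the list alone 0 members passed. Within 5 Mb of Dclk3, 149 genes were tested and 0 passed the threshold, and in a comparison chosen after seeing the data 5 (3.36%) had an unadjusted p under 0.05 against 3.75% elsewhere (Fisher's exact test, two-sided p = 1). Within 10 Mb, 10 of 238 genes did in the same comparison (4.2% against 3.74%, Fisher's exact two-sided p = 0.729). The planned Fisher test on genes past the threshold had nothing to compare, since 0 of them lay in either window.

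Libraries with odd and even replicate numbers differed in Mir6236, a locus annotated as a microRNA. The gene and the split were chosen after the values were seen, and each genotype has 2 libraries on either side. Which RNA the reads at Mir6236 came from was not tested. Mir6236 was counted at 4.39, 5.39, 5.49 and 4.92 CPM in the 4 odd-numbered libraries and at 1.38, 1.48, 1.76 and 1.97 CPM in the 4 even-numbered ones (adjusted p = 0.004, edgeR quasi-likelihood). The large mitochondrial ribosomal RNA mt-Rnr2 was at 27.6, 30.0, 28.8 and 31.4 CPM in the odd-numbered libraries and at 17.1, 19.4, 22.0 and 16.9 CPM in the even-numbered ones, but did not pass (adjusted p = 0.0835). Another mitochondrial ribosomal RNA, mt-Rnr1, chosen in the same way, did not pass either (adjusted p = 0.464, edgeR quasi-likelihood). It was at 26.9, 29.8, 27.6 and 27.4 CPM against 18.4, 21.1, 21.7 and 14.7 CPM. Within the odd-numbered libraries the knockout kept 27.6% of the wild-type Dclk3 level and within the even-numbered ones 20.8%, with 2 libraries per genotype in each. With the odd or even number as a covariate, Dclk3 was again the 1 gene past the threshold.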

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

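The tests of spiny neuron share, of RNAs without a poly(A) tail and of choroid plexus markers were chosen after the results they bear on had been seen. A library was set apart when its gap to the nearest of its group exceeded, as a share of the group's range, Dixon's limit for 4 values. This happened in 12 of 210 groups of values, where chance gives about 10.5. In wild-type replicate 4 the choroid plexus score was 3.42, Sst was at 108.8 CPM against at least 186.5 CPM and Aqp1 was at 25.6 CPM, against at most 1.26 CPM in the other wild-type libraries. In wild-type replicate 2 the blood cell score was -0.684, Hbb-bt was at 4.83 CPM against at least 9.18, and the reactive glia score was 0.172. Wild-type replicate 3 had a score of -0.0546 for other chromatin regulators. In knockout replicate 4 the heat shock score was 0.114, the score of genes near Dclk3 0.0817, Tekt1 2.08 CPM and Taf9 0.511 CPM, and knockout replicate 2 had 4232 CPM of mt-Nd2 against at least 4884 CPM in the other knockout libraries.

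The 8 libraries can be parted into groups of 4 in 35 ways. As many genes as the real split, 1, were called by 3 of the 35 splits, the real one included, so chance cannot be excluded for the count alone, and the highest other split called 5. That split set wild-type replicates 1 to 3 and knockout replicate 4 against the rest and its 5 genes were ENSMUSG00000044060, Gm26917, Mlip, Rorb and Rspo1, named after their values were seen. The split was singled out because it called the most genes. Its genes therefore cannot show by themselves that a structure of the samples crosses the genotypes. Rorb, a cortical marker, was at 37.7, 36.6, 38.4 and 37.8 CPM in wild-type replicates 1 to 3 and knockout replicate 4. It was at 62.8, 51.3, 49.6 and 51.7 CPM in wild-type replicate 4 and knockout replicates 1 to 3. Of the other cortical list members, Lamp5 went the same way, but Cux2, Neurod6 and Slc17a7 overlapped between the sides. Slc17a7 was at 735.6, 1159, 889.6 and 545.5 CPM against 894.7, 628.8, 881.8 and 801.7 CPM, in the same order of libraries. The split of odd against even replicate numbers called 1 gene, Mir6236 (adjusted p = 0.004, edgeR quasi-likelihood), and with that split as a covariate Dclk3 kept a log2 fold change of -2.06.

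Markers of astrocytes, oligodendrocytes, endothelium and blood ranked higher in the knockout with camera's preset correlation, but with an estimated correlation 0 of 35 lists passed (adjusted p 0.523, 0.757, 0.523 and 0.523). Of the 35 splits, 17 gave at least the 10 lists of the real split and the highest other gave 22, so chance cannot be excluded for this count. Adjacent tissue in some dissections was weighed by adding the choroid plexus and thalamic scores as covariates. With the preset correlation 4 of the 4 lists stayed past the threshold, which met the condition written against this source. With an estimated correlation 0 passed (camera adjusted p at least 0.766), but these lists had not passed with it before the scores were added. That result therefore cannot decide. Since chance is not excluded for the number of preset calls either, this source stays open too. A lower share of spiny neurons in the knockout tissue may also raise such markers, but the score of spiny neuron identity genes differed by 0.0403 (knockout minus wild type, SE 0.0767), too close to 0 against its error to decide. An effect of the genotype on these cell types remains open and untested beyond these counts.

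Malat1 was higher in all 4 knockout libraries without passing the threshold. A gene other than Dclk3 with a p as small as that of Malat1 appeared in 6 of the 35 splits, the real one included, where the real split held 1 such gene and the highest other 10, so chance cannot be excluded. More nuclear RNA in the knockout libraries would also raise other nuclear-retained RNAs. Their score differed by 0.0979, and with 2 standard errors by at most 0.223. This lies below 0.289, the bound of 0.5 of the Malat1 change. A smaller contribution of nuclear RNA is not excluded, since 15 of 18 members lay above 0. Without the lowest member their mean fold change reached up to 0.17 with 2 standard errors over members. Weaker poly(A) selection would raise RNAs without a poly(A) tail, of which 7 of 34 were measured. Their score differed by -0.34, and with 2 standard errors by at most 0.136, but 3 lay above 0 and 4 below. Without the lowest of them the mean fold change reached up to 0.359 with 2 standard errors over members, so this stays open. The members were measured in the same animals, so bounds over members do not cover differences between animals. A genotype effect on Malat1 itself is consistent with these values but is not separated from chance.

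Choroid plexus transcripts differed between libraries of the same genotype, with Ttr, chosen after its values were seen, at 44.7, 64.5, 23.7 and 2720 CPM in wild-type replicates 1 to 4 and at 208, 32.4, 68.5 and 66.4 CPM in knockout replicates 1 to 4. All 10 markers were highest in wild-type replicate 4, and their median pairwise correlation over the 8 libraries was 0.953. Their score was 3.42 in that library and between -1.04 and 0.46 in the others. A single library so far from the rest can bring about such a correlation by itself. The correlation therefore adds little to the high values in wild-type replicate 4 and does not show joint variation among the other libraries. The condition written for pieces of choroid plexus in single dissections asked for all markers to be highest in the same library of each genotype. Its part for wild type was met by replicate 4. Among the knockout libraries 8 of the 10 were highest in replicate 1, short of the 10 asked for. The condition as a whole was therefore not met, and this source remains possible but undecided for the knockout libraries. The knockout part does not bear on wild-type replicate 4, where the 10 markers were high together. No biological explanation was tested, since the design names no group that parts these libraries.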

How the results depend on the processing

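Dclk3 was past the threshold in 20 of 21 alternative settings, with log2 fold changes from -2.17 to -1.95 and adjusted p (edgeR, limma or DESeq2) from 2.91e-51 to 0.0647. With no filter on low counts it was at -2.07 and lost its call (adjusted p = 0.0647), while Malat1 gained one; the cause was not tested. The count of genes was 3 with DESeq2 and no filter (29371 genes; Dclk3, 1520401A03Rik and Malat1), 2 with DESeq2 on the filtered genes (Dclk3 and Malat1; chosen after seeing the data) and 3 with replicate 4 of each genotype left out, a setting chosen after seeing the data (Dclk3, Gm26917 and Gpr101). In the libraries left out there, Gm26917 and Gpr101 went the other way. Gpr101 was at 4.58 CPM in wild-type replicate 4 and 19.4 CPM in knockout replicate 4, and Gm26917 at 4.28 and 6.75 CPM. The count of genes was between 1 and 2 when single libraries were left out, 2 without wild-type replicate 1, the 1 wild-type library with 5 counts of 1520401A03Rik, which that fit calls. Fits without a knockout library call only Dclk3. Gene lists past camera numbered 0 with an estimated correlation and 0 with fry, and between 8 (without knockout replicate 4) and 16 (without wild-type replicate 2) when single libraries were left out. DESeq2 and the non-robust fit give no list test of their own. The camera result for all genes within 5 Mb (0.399) and 10 Mb (0.938) of Dclk3 pointed lower rather than higher, with neither past 0.05; this use of camera was chosen after seeing the data. Of 1400 values of 67 named genes under alternatives, 1393 kept direction and side of the threshold and 3, all Malat1, passed it. Dclk1 turned to 0.037 with 1 surrogate variable and to 0.025 without replicate 4 of each genotype, where Aqp1 turned to 0.19. Leaving out single libraries moved Aqp1 between -3.19 and 0.12, the latter without wild-type replicate 4. The cause of the other reversals was not tested. Deviations of same-numbered libraries correlated at -0.276 to 0.0532, and 1 of 8 libraries correlated best with its own number. No pairing by number was thus seen over all genes. Differences between single dissections enter these correlations, so they cannot exclude that the numbers mark something shared. Odd and even numbers differed in Mir6236, but that gene and split were chosen after seeing the data. The Mir6236 difference therefore cannot decide this by itself. The replicate block again called 1 gene. At this depth a gene at 0 counts could hold up to 0.0808 to 0.123 CPM.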

Other observations

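Single animals stood apart in small sets of genes. These genes were chosen after their values were seen. Among 15327 genes with at least 30 counts in a library, 134 had a gap between libraries larger than 1 on the log2 scale (0.1 CPM added) and larger than the spread on either side of it. In 74 of them wild-type replicate 4 was above the other libraries, in 25 wild-type replicate 2 was, and in 16 knockout replicate 4 was. The 74 genes include the whole fixed list of choroid plexus markers, Ttr, Kl, Folr1, Clic6, Kcnj13, Aqp1, Otx2, Sostdc1, F5 and Prlr. The rest of the 74 were not assigned to a tissue. In 5 genes the gap parted several libraries from several others, namely Dclk3, 1520401A03Rik, Gal, Mir6236 and Mrgprf.

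Several of the genes above the others in knockout replicate 4 are known from inflammation, a grouping that was chosen after the values were seen and was not tested. In that library the score of the fixed list of reactive glia and inflammation was 0.0425, below knockout replicate 2 (0.0636) and wild-type replicate 2 (0.172), and the cytokine gene Il12a was lowest (0.438 against 1.02 to 2.03 CPM). Lcn2, an acute-phase siderophore-binding protein gene, was at 6.28 CPM against 0.0341 to 0.205 CPM in the other 7 libraries. Sele, which encodes the endothelial adhesion molecule E-selectin, was at 4.12 CPM against 0 to 0.144 CPM, Ch25h, cholesterol 25-hydroxylase, at 5.07 against 0.172 to 0.274 CPM, and the chemokine gene Cxcl1 at 1.72 against 0 to 0.205 CPM. Lrg1 was at 2.12 CPM against 0.215 to 0.580 CPM and Plin4, a lipid droplet gene, at 24.7 against 1.76 to 3.94 CPM. The same library had the highest level of Prkcd, a thalamic marker, at 167 CPM against 10.6 to 69.9 CPM. Wild-type replicate 2 had 8.08 CPM of the glycine transporter gene Slc6a5 against 0 to 0.182 CPM elsewhere, 322 CPM of the secretory granule gene Chga against 124 to 155 CPM, and 18.7 CPM of Tmem40 against 1.5 to 3 CPM.

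A few genes were present or absent in single animals. 1520401A03Rik on chromosome 17 (23704488 to 23722783, minus strand, GRCm38) had 797, 942 and 802 counts in wild-type replicates 2, 3 and 4 but 5 in wild-type replicate 1, and 5, 5, 6 and 5 in knockout replicates 1 to 4. The filter on low counts removed it, since only 3 libraries reach the minimum, DESeq2 called it with an adjusted p of 3.57e-05, and without wild-type replicate 1 edgeR's quasi-likelihood test called it with an adjusted p of 2.85e-08. Low counts were thus found in all 4 knockout animals and in 1 of 4 wild-type animals. Whether the animals share a genetic background is not given in the sources used here, so these values are not assigned to the genotype. Gm15446 on chromosome 5 had 0 counts in knockout replicate 2 and 181 to 547 counts in the other 7 libraries. Gm4750 on chromosome X had 380 counts in wild-type replicate 3 and at most 4 in the others.

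Xist had at most 2 counts in a library, and the Y-linked gene Ddx3y was at 74.2 to 89.5 CPM in all 8. Another Y-linked gene, Eif2s3y, was at 15.2 CPM in knockout replicate 4 and at 34.8 to 48.3 CPM in the other libraries, and Col5a1 was at 10.7 CPM there and at 26.8 to 40.2 CPM elsewhere.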
